A study of Mus musculus with 2 samples.

How the data were processed

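Poly(A) RNA was profiled in 2 samples of mouse eye lens, 1 of cortical fiber cells and 1 of epithelial cells. The lenses came from 5 mice aged 13 days and were dissected with forceps into the capsule with its adhering epithelium and the cortical fibers. Whether the lenses of the 5 mice were pooled is not given in the sources used here. Per the labels, RNA was copied into biotin-labelled complementary RNA and hybridized to a 1-colour CodeLink mouse bioarray, stained with a Cy5 conjugate, and the image was analysed with the CodeLink software. The free-text description of both samples speaks of fetal liver RNA, while their titles, source names and the series design name the lens. The array type, staining and image analysis are known from that same description. The samples were grouped by their source names, and markers of liver and erythroid cells were examined for this reason.

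The deposited table holds 1 intensity per probe and array for 19819 probes. The deposited intensities are on a linear scale, since they run from below 0 up to 5411, and each array's median lies close to 1 (0.998 for both). The scaling and background steps the authors applied are not given in the sources used here, and the values below 0 (161 on the cortex array, 74 on the epithelium array) are those of a background-subtracted signal. No detection call or spot flag was used here. Values were missing for 87 probes on the cortex array and 97 on the epithelium array, 84 of them on both, and such probes were left out. Genes were named through the platform annotation, in which 15120 probes had 1 gene symbol, 38 had several and 4661 had none. Of the probes with 1 symbol, 15064 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and no symbol changed. Probe sequences and positions were not used here, so no genome coordinates are given.

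The deposited scaling was kept. A floor was set at 0.5 of each array's median (0.499 on both arrays), values below it were raised to it, and log2 was taken. The floor was taken over all probes, since control probes are not marked in the table. Of the probes with a value, 65.5% on the cortex array and 60.9% on the epithelium array lay above the floor. The floor is not a detection limit of the platform. Differences are log2 cortex minus log2 epithelium. Where a gene had several probes, the 1 with the highest mean log2 value was used, which left 13709 genes. A gene above the floor on 1 array alone has only a bound, given as "at least N-fold", and a gene at the floor on both arrays was given a difference of 0.

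With 1 array per sample there is no replicate, so no test across samples was possible and no p-value is given for any gene. A rule of size was used instead: a gene was counted as higher in 1 sample when it was at least 3-fold brighter there and that array lay at or above its median. The only error the table can give is the spread between different probes of a gene, which is technical and holds no biological variation. Over 558 genes with 2 or more probes above the floor on both arrays, the pooled SD of the log2 difference between probes was 1.10 and the median SD was 0.59. The number of arrays limits the precision of every value.

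For 30 gene lists, the median log2 difference was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 arrays and is not a test between conditions. The lists, the 3-fold rule and the rule for named genes were written before the data were examined, and 3 further lists were added afterwards. The named genes are the 12 with the largest difference in each direction among genes above the floor on both arrays, the 5 with the largest bound in each direction, all members of the crystallin, fiber, epithelial and nuclease lists, and up to 4 members of each other list with the largest absolute difference. Genes named outside this rule are marked as such.

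The procedure was tested on simulated data of the 13709 genes, in which 100 were changed 4-fold and 100 were changed 16-fold. The changed genes were drawn from those with a mean log2 value above 2, so recovery of dimmer genes was not tested. With noise at the median SD between probes, 77.0% of genes changed 4-fold and 100% of genes changed 16-fold were recovered, and 51 unchanged genes were called. With noise at the pooled SD, 70.0% of genes changed 4-fold and 100% of those changed 16-fold were recovered, and 1118 unchanged genes were called. Alternatives were quantile normalization, a loess correction of the difference on brightness (span 0.3), centring on ribosomal protein genes, no floor, a floor at the median, the mean over probes, fold limits of 2 and 5, other filters on dim genes, and other summaries of the lists. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.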

Results

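Gene expression was compared between the cortical fiber cells and the epithelial cells of the lens of 13-day-old mice, with 1 array for each. The lens epithelium is a monolayer of dividing and quiescent cells beneath the anterior capsule. Its cells withdraw from the cell cycle, elongate and become fiber cells, which fill with crystallins and later lose their nuclei and organelles. The comparison asks which genes differ between the 2 cell populations. The values are normalized intensities, in units of each array's median. They ran up to 5411 on the cortex array and 1061 on the epithelium array, with upper quartiles of 5.08 and 4.84. No value below has a replicate, so each difference is 1 array against 1 array. The pooled SD between probes of the same gene, 1.10 on the log2 scale, is the only measure of error.

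Of 13709 genes, 1290 were at least 3-fold higher in cortex and 1120 were at least 3-fold higher in epithelium. Among the first, 188 were at the floor in epithelium, and among the second, 266 were at the floor in cortex. A further 7936 genes above the floor on at least 1 array did not pass. Of these, 6395 were measured on both arrays and differed by less than 3-fold, and 1541 were above the floor on 1 array alone, so that their bound lay under 3-fold and their difference is not known. The other 3363 were at the floor on both. Across genes, the log2 values of the 2 arrays correlated with a Pearson r of 0.84 and a Spearman rho of 0.84 (genes are not independent replicates). Over the genes above the floor on both arrays alone, the Pearson r was 0.76. The split between directions depended on the scaling. Cortex took 53.5% of the calls with the deposited scaling and 19.9% after centring on ribosomal protein genes, which moved the median difference of genes above the floor on both arrays from 0.03 to -0.73. That median was -0.11 after quantile normalization and -0.08 after loess. Simulated noise at the pooled SD between probes called 1118 unchanged genes, and noise at the median SD called 51. The share of calls that noise could give therefore depends on the SD used, and a call near 3-fold carries little weight without a second probe. For 25 of the 106 called genes named here with a measured fold, the dimmer value lay between the floor and its array median, and the size of the fold then depends on the floor. Where a called gene had another probe above the floor on at least 1 array, the brightest such probe was also at least 3-fold different in the same direction for 30 of 115 genes higher in cortex (26.1%) and 24 of 76 genes higher in epithelium (31.6%). Over all called genes with a second probe the shares were 30 of 172 (17.4%) and 24 of 110 (21.8%), and 6 and 2 second probes were at least 3-fold different in the opposite direction. These shares count second probes above the floor on 1 array alone, whose difference is a bound. Of 150 other probes of called genes above the floor on both arrays, 102 (68.0%) went in the same direction, 45 of them by at least 3-fold.

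**Figure D1:**
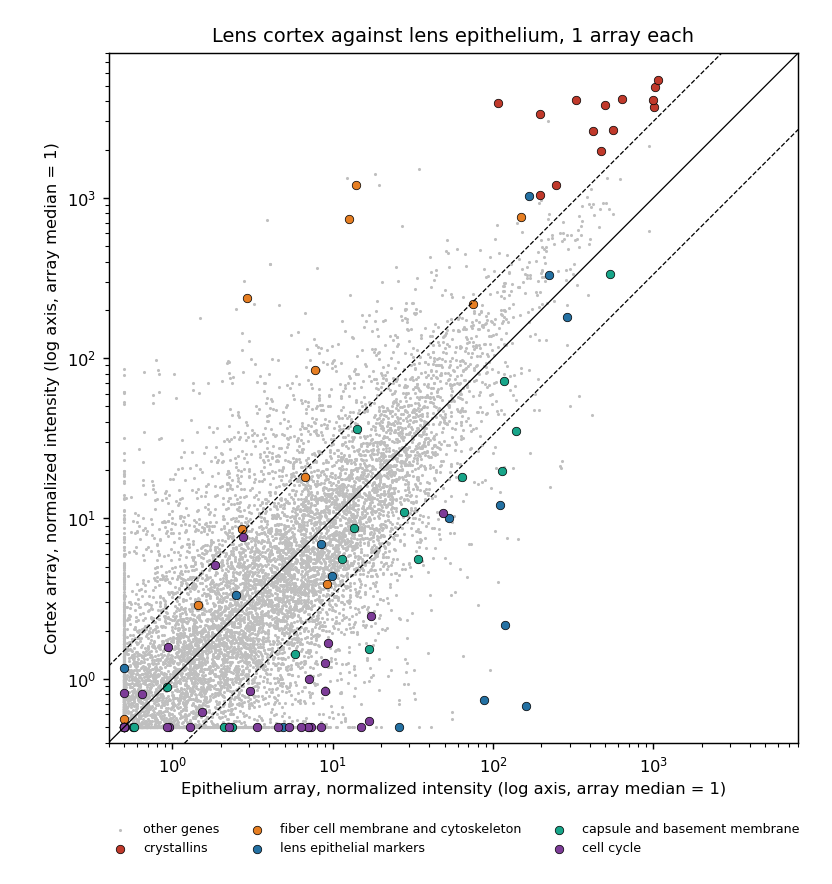
Normalized intensity of each gene on the epithelium array (x axis) and the cortex array (y axis), both log axes in units of the array median, with values under the floor drawn at the floor. Points are genes, the solid line marks equality and the dashed lines 3-fold; all 14 crystallins lie above the upper dashed line with the deposited scaling, and 17 of 29 cell cycle genes lie below the lower one.

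All 14 measured crystallins, the refractive proteins of the lens, were at least 3-fold higher in cortex with the deposited scaling, with a median log2 difference of 2.38. That median lay at percentile 99.99 of brightness-matched random lists. The α- and β-crystallins differed by 3.65-fold (Cryab, 3708 against 1015) to 6.49-fold (Cryba4, 4124 against 635). Cryaa stood at 1951 in cortex and 468 in epithelium, a 4.17-fold difference. The γ-crystallins spread more widely. Crygs differed 4.15-fold, Crygc 6.19-fold, Crygb 7.69-fold, Cryga 12.4-fold, Crygd 17.1-fold and Crygf 36.6-fold (3913 against 107). These genes include near-identical copies whose probes may share signal, so the separate γ-crystallin values are uncertain. Crystallins held 18.5% of the summed intensity of all genes in cortex and 5.72% in epithelium. Their fold differences depended on the scaling, because the brightest genes as a class were brighter in cortex. After quantile normalization, and likewise after loess on brightness, 3 of the 14 remained at least 3-fold higher, and after centring on ribosomal protein genes 6 did. After quantile normalization Cryab (log2 difference -0.25) and Crybb1 (-0.30) changed direction. That method gives equal ranks equal values, and crystallins were among the brightest genes on both arrays. It therefore removes much of their difference by design, and the 2 changed signs compare ranks, not a higher level in epithelium. The list median stayed above 0 in each scaling, with 0.71 as its lowest value.

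Genes of fiber cell membranes and cytoskeleton were also higher in cortex. Of 12 measured, 6 were at least 3-fold higher in cortex and none in epithelium, with a median log2 difference of 1.60 at percentile 99.83 of matched random lists. Hspb1, a small heat shock protein, was 86.4-fold higher (1197 against 13.9). Lgsn (lengsin) was 81.8-fold higher and Bfsp1 (filensin, of the beaded filament) 58.8-fold higher. Mip (aquaporin 0) was 10.8-fold higher (83.8 against 7.72), Grifin, a lens galectin-related protein, 5.04-fold and Cap2 3.19-fold. The gap junction gene Gja3 (218 against 75.4, 2.89-fold) and Lim2 (18.1 against 6.72, 2.70-fold) stayed under the limit. Epb41l1 differed 2.01-fold, and Cdh2 was 2.36-fold brighter in epithelium, also under the limit. Tmod1 was at the floor on both arrays and Ank2 near it. The count was 5 after quantile or loess normalization and 4 after centring on ribosomal protein genes, where Cdh2 passed the limit in the direction of epithelium.

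The epithelial markers showed the opposite pattern in part. Of 21 measured, 8 were at least 3-fold higher in epithelium, 1 was higher in cortex and 12 did not pass, with a median log2 difference of -0.28 at percentile 0.43. Igfbp5, a secreted binding protein of insulin-like growth factors, stood at 161 in epithelium and 0.672 in cortex. A second, dimmer probe stood at 0.507 in epithelium and under the floor in cortex, so its difference is not known. Sulf1, a heparan sulfate sulfatase, was 119-fold higher in epithelium, and the growth factor receptor gene Pdgfra 54.6-fold. The second probes of Sulf1 (-2.47) and Pdgfra (-1.45) were under the floor in cortex, so these 2 differences are bounds. Cdh1 (E-cadherin) was at least 52.2-fold higher, the water channel gene Aqp1 at least 14.3-fold and the transcription factor gene Foxe3 at least 9.86-fold. The glucose transporter gene Slc2a1 (9.07-fold) and Ccnd2 (5.28-fold) completed the group. Cd24a went the other way (1027 in cortex against 167, 6.14-fold), though it was under 3-fold after quantile or loess normalization. Clu, Wls, Fgfr3, Sfrp1 and Itga6 differed by less than 3-fold, Npnt (at least 2.34-fold brighter in cortex) and Gja1 (at least 1.14-fold brighter in epithelium) had bounds under 3-fold, and Ccnd1, Igfbp3, Mt2, Sfrp2 and Sfrp5 were at the floor on both arrays. Some markers of neighbouring tissue were higher on the epithelium array too. Of 9 ciliary body genes, 3 were higher there and none in cortex: Ptgds (123 against 7.54), Msx1 (8.36 against 1.07) and Gpx3 (at least 3.10-fold). With the floor at the array median the count was 2, without Gpx3. Of 10 pigment cell genes, Oca2 (9.09 against 0.521) and Tyrp1 (at least 6.62-fold) were higher in epithelium and Dct (at least 3.95-fold) in cortex. Dct did not pass with the floor at the array median.

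Cell cycle genes were lower in cortex. Of 29 S phase and mitosis genes, 17 were at least 3-fold higher in epithelium and none in cortex, with a median log2 difference of -2.18, below the medians of all 10000 matched random lists. Mki67, the proliferation antigen Ki-67, stood at 16.8 in epithelium and near the floor in cortex (0.542), which is at least 16.8-fold with the floor at the array median. With the floor used throughout, Mki67 differed 30.9-fold, Cdk1 by at least 30.0-fold, Ccnb2 by at least 16.9-fold and Cks2 by at least 14.7-fold. Of 12 cell cycle inhibitor genes, 4 were higher in cortex and 2 in epithelium. The growth arrest and DNA damage genes Gadd45b (24.4-fold) and Gadd45a (18.6-fold) were higher in cortex, and Gas1 (8.16 against 0.601, at least 8.18-fold with the floor at the array median) and Btg1 (12.4-fold) were higher in epithelium.

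Capsule and basement membrane genes were lower in cortex as well. Of 18 measured, 8 were at least 3-fold higher in epithelium and none in cortex, with a median of -1.20, below the medians of all matched random lists. The laminin chain gene Lamc1 was 11.0-fold higher in epithelium, and the collagen IV genes Col4a4 and Col4a2 were 6.09-fold and 5.71-fold higher. A second probe of Col4a4 differed by -0.35. Fbln1 was at least 4.69-fold higher, with a second probe at the floor on both arrays. The list median was -1.88 after quantile normalization, with 11 genes higher in epithelium. With the floor at the array median 6 genes were higher there, and Fbln1 no longer passed.

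Transcription and RNA factors of lens development split. Of 21 measured, 4 were at least 3-fold higher in cortex and 2 in epithelium, with a median of -0.36 (percentile 2.84, within the range of random lists). Hsf4, a heat shock factor of the postnatal lens, was 25.4-fold higher in cortex (139 against 5.46), and Tdrd7, a component of RNA granules, 14.9-fold higher. Id3, an inhibitor of helix-loop-helix factors, was 15.4-fold higher in epithelium, and Foxe3, given above, was higher there too. After quantile or loess normalization 4 were higher in epithelium, and after centring on ribosomal protein genes 3 were higher in cortex and 6 in epithelium.

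**Figure D2:**
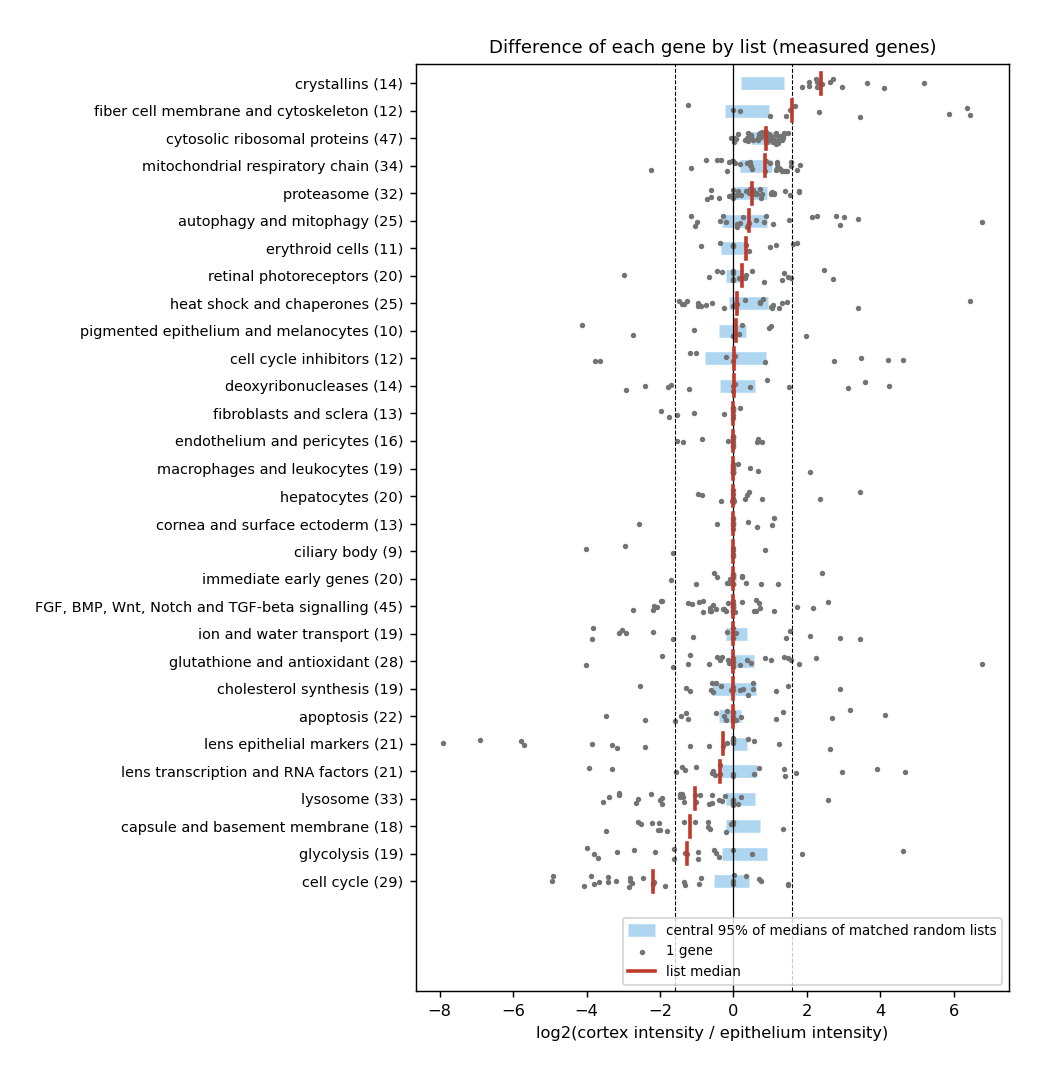
Log2 ratio of cortex to epithelium intensity (x axis) of each measured gene of the 30 lists (number of measured genes in brackets), with the list median (red) and the central 95% of medians of 10000 brightness-matched random lists (blue). Dashed lines mark 3-fold; the medians of crystallins and of fiber genes lie to the right of the blue range, and those of cell cycle, glycolysis, capsule, lysosome and epithelial lists lie to its left.

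Fiber cells lose their nuclear DNA as they mature, and the genes of DNA degradation were therefore examined together. Of 14 measured, 3 were at least 3-fold higher in cortex and 4 in epithelium, and the list median of 0.02 lay within the range of random lists. Dnase2b, which encodes the DNase II-like acid DNase, was 8.64-fold higher in cortex (28.4 against 3.29). Its relative Dnase2a, encoding the lysosomal DNase II, differed in the other direction (14.6 against 110, 7.56-fold higher in epithelium). The exonuclease gene Trex1 was higher in cortex (70.2 against 3.70). Dffa, the inhibitor of the caspase-activated DNase, was also higher in cortex (119 against 9.91), while the DNase gene itself, Dffb, stood at 2.61 against 0.913, a 2.85-fold difference under the limit. Dnase1l1 (5.29-fold), Dnase1l2 (3.43-fold) and Fen1 (at least 3.22-fold) were higher in epithelium, the last with 1.61 as its brighter value. Aifm1 (2.34-fold brighter in epithelium), Apex1 (50.1 against 37.0) and Nme1 (53.7 against 28.7) did not pass, Endog stood at 0.537 and 0.522, and Dnase1l3 and Trex2 were at the floor on both arrays. With a floor at the array median, Dnase1l2 and Fen1 no longer passed, and 5 of the 14 remained. After loess on brightness Dffb passed as well. The calls of Dnase2b, Dnase2a, Trex1, Dffa and Dnase1l1 held in each scaling tried.

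**Figure D3:**
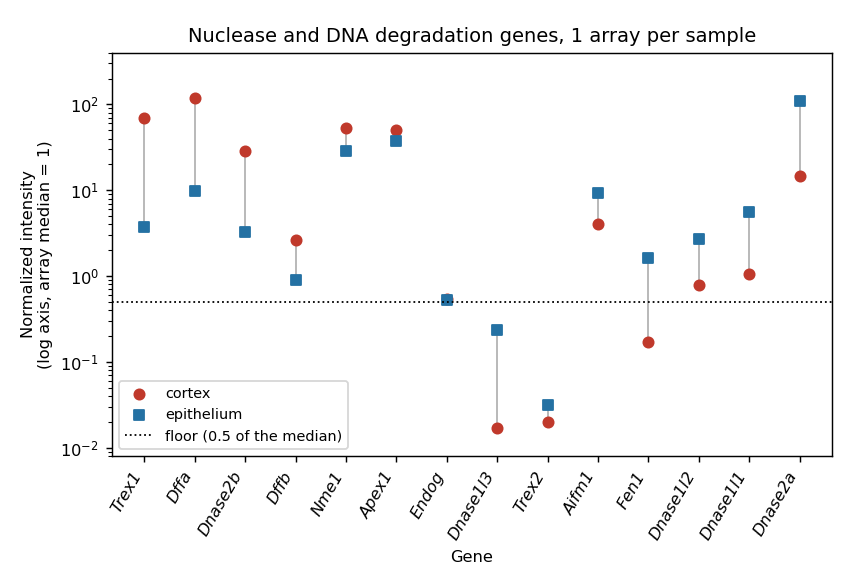
Normalized intensity (log axis, units of the array median) of 14 nuclease and DNA degradation genes on the cortex array (red circles) and the epithelium array (blue squares), with the floor as a dotted line and no error bars because each sample has 1 array. Dnase2b lies at 28.4 in cortex and 3.29 in epithelium, and Dnase2a at 14.6 and 110.

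Lysosomal genes as a group were lower in cortex, in contrast to Dnase2b. Of 33 measured, 10 were at least 3-fold higher in epithelium and 1 in cortex, with a median of -1.04, below the medians of all matched random lists. The count in epithelium was 14 after loess, 15 after quantile normalization and 19 after centring on ribosomal protein genes, where the median was -1.93. The cathepsin genes Ctsl (22.8 against 268, 11.8-fold) and Ctsh (8.61-fold), the glucuronidase gene Gusb (10.5-fold) and the membrane protein gene Cd63 (8.67-fold) differed most. The exception was Atp6v1b2, a subunit of the vacuolar proton pump, at 51.0 in cortex against 8.61, named after its value was seen. Of 25 genes in the autophagy list, 7 were at least 3-fold higher in cortex and none in epithelium, but the median of 0.44 lay within the range of random lists (percentile 65.5). After centring on ribosomal protein genes the counts were 5 in cortex and 3 in epithelium, and the median was -0.45. The genes higher in cortex included Atg3, the conjugating enzyme of the LC3 family (7.44-fold). They also included list members that are not part of the autophagy machinery itself. These were the phospholipase genes Plaat3 (10.6-fold) and Plb1 (8.04-fold), and Hmox1 (heme oxygenase 1), at 1327 against 12.2.

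Glycolytic genes were lower in cortex, with 8 of 19 at least 3-fold higher in epithelium, 2 higher in cortex and a median of -1.27, below the medians of all matched random lists. Pfkm (8.42 against 0.534, at least 8.44-fold with the floor at the array median) and Pfkp (13.8-fold, at least 11.3-fold with that floor), which encode phosphofructokinases, were higher in epithelium. Ldha (lactate dehydrogenase A, 12.9-fold) was higher there too. Pgam2, the muscle form of phosphoglycerate mutase, was 24.7-fold higher in cortex (663 against 26.9). The count in epithelium was 11 after loess and 12 after quantile normalization or centring on ribosomal protein genes, with a lowest median of -2.16.

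Genes of protein synthesis, respiration and protein turnover were moderately brighter in cortex with the deposited scaling, to a degree that brightness-matched random lists shared. None of 47 ribosomal protein genes passed 3-fold, and their median difference was 0.89 (percentile 68.1), with Rpl7 highest at 2.79-fold. Of 34 respiratory chain genes, 2 were at least 3-fold higher in cortex (Cox7c, 3.50-fold, and Ndufa1, 3.31-fold) and 1 in epithelium (Atp5j, 4.74-fold), with a median of 0.87 (percentile 85.3). Of 32 proteasome genes, 2 passed in cortex (Psmd3, 3.46-fold, and Psmc4, 3.41-fold), with a median of 0.50. The ribosomal median turned to -0.28 after loess on brightness and -0.29 after quantile normalization. The respiratory chain median became 0.00 and -0.07 and the proteasome median -0.01 and -0.06, and no respiratory chain or proteasome gene stayed 3-fold higher in cortex, so no direction can be given for these groups.

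The remaining pathway lists had counts in both directions or few calls, and their medians lay within the central 95% of random lists, which says little for the signalling list, where that range was 0 to 0. Of 22 apoptosis genes, 3 were higher in cortex (Pmaip1, at least 17.5-fold, Fas, 9.05-fold, and Bbc3, 6.38-fold) and 3 in epithelium, among them Casp6 at 11.0-fold, whose second probe differed by 0.82 in the other direction. Of 25 chaperone genes, 2 passed with the deposited scaling, both in cortex (Hspb1 and Dnajb1, the latter 10.4-fold). A further 3 passed in epithelium after quantile or loess normalization, and 7 after centring on ribosomal protein genes, so the list has no settled direction. Of 28 glutathione and antioxidant genes, 3 were higher in cortex, including Hmox1 and Gstp1 (4.78-fold), and 3 in epithelium, including Gstm2 (16.3-fold) and Gstt1 (at least 3.86-fold). That balance became 1 and 4 after quantile or loess normalization. With the floor at the array median it was 3 and 1, and Gstt1 no longer passed. Of 19 ion and water transport genes, 3 were higher in cortex and 7 in epithelium, including the sodium pump subunit genes Atp1b3 (14.2-fold) and Atp1b1 (8.60-fold, at least 7.12-fold with the floor at the array median). Of 45 growth factor signalling genes, Smad1 (5.96-fold) and Spry1 (4.52-fold) were among 3 higher in cortex. Tgfb1 (6.69-fold) and Acvr1 (4.60-fold, at least 3.03-fold with the floor at the array median) were among 6 higher in epithelium. The counts of signalling genes were 1 and 10 after centring on ribosomal protein genes. Of 19 cholesterol synthesis genes, Dhcr7 was 7.48-fold higher in cortex and Ebp 5.85-fold higher in epithelium. Of 20 immediate early genes, Zfp36 passed in cortex (5.29-fold) and Klf4 in epithelium (at least 3.28-fold), though Klf4 did not pass with the floor at the array median.

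Beyond the lists, the genes with the largest measured differences in the direction of cortex were Pcgf2 (189-fold, 731 against 3.87), Cd8b1 (124-fold), Ksr1 (123-fold), Hoxd1 (120-fold), Hmox1 (108-fold), Unc5d (108-fold), 4933406C10Rik (104-fold), Ccdc33 (96.4-fold), Nfatc2 (95.9-fold), Cntnap1 (94.6-fold), Hspb1 and Slc46a2 (82.1-fold). The largest bounds were those of Ceacam10 (at least 173-fold), Slc1a2 (at least 157-fold), Dcpp1 (at least 124-fold), Pde10a (at least 123-fold) and Vmn1r14 (at least 122-fold). Second probes of Ksr1, Unc5d, Slc1a2 and Dcpp1 were at the floor on both arrays, and that of Pde10a differed by -0.52, so none repeated the call. Whether the probes of the genes in this group report the genes they are named for is therefore not known. Vmn1r14 is 1 of 73 chemosensory receptor genes that were at least 3-fold higher in cortex, against 1 in epithelium. In the direction of epithelium, Igfbp5, Sulf1 and Pdgfra, given above, stood with Adamtsl4 (98.8-fold), Antxr1 (88.5-fold), Inppl1 (83.9-fold), Pdpn (podoplanin, 46.5-fold), Mdfic (44.0-fold), Erh (39.4-fold), Pla2g4a (37.1-fold), Dock9 (35.0-fold) and D17H6S56E-5 (31.4-fold). With the floor at the array median, the differences toward epithelium of Igfbp5, Sulf1, Adamtsl4, Antxr1, Mdfic, Erh, Pla2g4a, Dock9 and D17H6S56E-5 are bounds, of at least 55.7-fold for Adamtsl4 and 55.4-fold for Antxr1, and those of Cd8b1, Ksr1, 4933406C10Rik and Nfatc2 toward cortex are bounds too, so the order among these genes is uncertain. Toward epithelium, the largest bounds with the floor used throughout were those of Ifi27 (at least 82.3-fold), Slc15a2 (at least 69.5-fold), Cdh1, Tmem35a (at least 50.8-fold) and Scel (sciellin, at least 50.4-fold).

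Markers of cell types outside the lens were mostly dim. Because the sample descriptions mention fetal liver, hepatocyte and erythroid genes were of particular interest. Of 20 hepatocyte genes, 9 were at the floor on both arrays, Afp (α-fetoprotein) stood at 0.660 in cortex and 0.680 in epithelium, and Apoa1 at 0.242 and 0.228. Ahsg (185 in cortex against 16.9) and Apoc1 (2.76 against 0.542) were the 2 higher in cortex. Of 11 erythroid genes, the α-globin gene Hba-a1 stood at 1.39 in cortex and 1.79 in epithelium, and Rhag (3.29-fold) and Epb42 (3.08-fold) were higher in cortex. Afp, Apoa1 and Hba-a1 were chosen after their values were seen. With the floor at the array median, Epb42 and Apoc1 no longer passed. Of 19 macrophage and leukocyte genes, 15 were at the floor on both arrays, and Cd79a was 4.20-fold higher in cortex. None of 16 endothelial and pericyte genes passed 3-fold. Of 13 fibroblast genes, Col5a1 (3.94-fold) and Col1a2 (at least 3.35-fold) were higher in epithelium, but with values of at most 2.20, and neither passed with the floor at the array median. Of 20 photoreceptor genes, Guca1b (6.52-fold) and Cnga1 (5.55-fold, at least 3.04-fold with the floor at the array median) were higher in cortex and Rom1 (at least 7.94-fold) in epithelium. Of 13 corneal genes, Tkt (transketolase) was 5.90-fold higher in epithelium. The erythroid median of 0.35 lay at percentile 97.3 of matched random lists, within their central 95%, and outside it after loess on brightness (98.6) and quantile normalization (98.1). The photoreceptor median of 0.23 lay at percentile 96.9 and outside after quantile normalization (97.7), with a floor at the array median (99.9) and over members above the floor on both arrays (99.9, with a median of 1.33). For the hepatocyte, leukocyte, endothelial, fibroblast and ciliary body lists many members were at the floor, the median and the random range were both 0, and the percentile of that median gives no information. Over its 3 members above the floor on both arrays, the ciliary body list had a median of -2.96 at percentile 0.120. With means in place of medians, the fibroblast list lay at percentile 1.02, the ciliary body list at 0.610, the ion and water transport list at 1.62 and the autophagy list at 98.7, all outside the central 95%.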

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

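The counts of 1290 genes higher in cortex and 1120 in epithelium stayed within 1.5 times under quantile normalization, loess on brightness, no floor, a floor at the array median, the mean over probes and a filter on genes above the floor on both arrays. The least bright probe of each gene, chosen after seeing the data, could change only the 1247 genes with 2 or more probes. Among the called genes these were 172 of the 1290 and 110 of the 1120, and all other calls were shared by construction. With these included, 1145 of the 1290 and 1033 of the 1120 calls were shared, which says little about agreement between probes. In the opposite direction, 7 genes were called. Centring on ribosomal protein genes gave 606 and 2440, because it lowers every cortex value alike. A 2-fold limit gave 2243 and 2101, and a 5-fold limit 698 and 477. Dropping the demand on the brighter array changed nothing, since any gene 3-fold above the floor already meets it. The crystallin median of 2.38 became 0.71 after quantile normalization, 0.98 after loess and 1.49 after centring on ribosomal protein genes. Cryab (-0.25) and Crybb1 (-0.30) reversed after quantile normalization, which compares only ranks among the brightest genes. The other medians of the fiber and epithelial lists stayed within their bootstrap intervals. Of 30 lists, 7 lay outside the central 95% of random lists; the count was 11 with means instead of medians and 12 with random lists not matched on brightness, and it lay between 7 and 9 otherwise. The same 7 lists (5 low, 2 high) stayed outside under all these settings. The Pearson correlation of 0.84 across genes became 0.828 after centring on ribosomal protein genes, 0.829 with no floor and 0.830 with a floor at the median. Over genes above the floor on both arrays alone it was 0.759. The cause of these shifts was not tested unless stated. No paired analysis was possible because each group has 1 sample, and for the same reason no replicate could be left out. Among 187 named genes, 23 moved by more than the pooled SD between probes after loess, 20 after quantile normalization besides the 2 that reversed, 14 with no floor and 11 with the mean over probes. Signal near the floor limits the dim genes, whose fold differences are bounds.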

Other observations

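The 3 gene lists added here and all tests in this part were chosen after the data had been seen. Of 25 measured genes in a list of interferon response and class I antigen presentation, 8 were at least 3-fold higher in epithelium and 1 in cortex. Of the antigen presentation members, B2m alone passed, and Tap1, Psmb8, Psmb9 and H2-Q7 were at the floor on both arrays. Ifi27 was at 41.1 in epithelium, Ifitm2 at 54.2 against 8.15, B2m (β2-microglobulin) at 25.3 against 1.57 and Ifitm3 at 11.5 against 0.603, while Irf1 was higher in cortex (133 against 13.3). The list median was 0.00, at percentile 45.3 of matched random lists, since many members were dim. Without Ifi27, Ifitm3 and B2m, which prompted the list, 5 of 22 were higher in epithelium.

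DNA damage response genes of the p53 pathway were also listed. Of 23 measured, 7 were at least 3-fold higher in cortex, 2 in epithelium and 14 did not pass, with a median of 0.27 (percentile 96.1, within the central 95% of random lists). Ccng1 (cyclin G1) stood at 80.4 against 2.25 and Plk2 at 4.34 against 0.867, beside Gadd45a, Pmaip1, Fas and Bbc3 given above. The 2 genes higher in epithelium were Phlda3 (3.82-fold) and Polk (at least 3.28-fold). Cdkn1a, another p53 target in the list, was at the floor on both arrays. Without Ccng1, Gadd45a and Pmaip1, which prompted the list, 4 of 20 were higher in cortex, and the median of 0.15 lay at percentile 91.9, also within that range. Of 20 genes of the integrated stress response, 3 were higher in cortex, including Ppp1r15a (219 against 3.23), and all 3 had prompted the list. A further 3 were higher in epithelium, among them the serine synthesis gene Phgdh (16.4 against 1.35). Among 4633 probes with no gene symbol and values on both arrays, 406 were at least 3-fold higher in cortex and 164 in epithelium.

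Crystallins were bright on the epithelium array, where Cryba2, Cryba1 and Cryab were the 3 brightest genes. One technical explanation is fiber RNA carried over into the epithelial sample. Carryover of RNA with the composition of the cortex sample would give every fiber gene at least the same ratio of epithelium to cortex. The third lowest ratio among the genes of the fiber list that were bright in cortex, that of Bfsp1, was 1.70%, or 7.77% with 2 SD between probes added. Other fiber genes had higher ratios, 9.22% for Mip, 19.9% for Grifin and 34.6% for Gja3. The lowest ratio among the 8 α- and β-crystallins was 15.4% (Cryba4). Crybb3 and Crybb2, which were about as bright in cortex as Hspb1 (1.16%), had ratios of 18.8% and 20.5%. If the limit from Hspb1, Lgsn (1.22%) and Bfsp1 holds, these ratios argue against carryover of RNA with the cortex composition as the whole source of the α- and β-crystallin signal. That limit rests on these 3 genes, with 1 probe each. A limit set by Mip with 2 SD added would lie above the α- and β-crystallin ratios and would not exclude carryover. The limit does not hold for fiber RNA of another composition, so carryover of such RNA remains open. Among the 6 γ-crystallins the lowest ratio was 2.73% (Crygf) and 2 lay within that limit, so carryover remains open for Crygf and Crygd, and a compressed signal of the brightest spots and epithelial transcription of crystallins remain open for the list.

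The group-wide shift of ribosomal protein genes toward cortex may come from a difference in scale between the arrays that grows with brightness. Genes above the floor on both arrays had a median difference of 0.75 in the brightest of 10 equal bins and between -0.22 and 0.17 in the other bins, and the ribosomal median lay at percentile 68.1 of lists matched on brightness, as that explanation predicts. A real rise of abundant transcripts in fiber cells would give the same picture, and 1 array per sample does not separate these.

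Chemosensory receptor genes (olfactory, vomeronasal and taste) were unevenly split. Of 647 measured, 73 were at least 3-fold higher in cortex and 1 in epithelium, where 1000 random lists matched on brightness had medians of 30 and 37, at most 47 for cortex and at least 21 for epithelium. Olfr516 reached 453 in cortex against 52.1, and the counts were 38 and 6 after centring on ribosomal protein genes and 70 and 2 after quantile normalization. Over all 647, the median was 0.617 in cortex and 0.325 in epithelium and the median excess 0.270, against a shift of 0.150 in the lower quartile of all probes; with 0.270 subtracted from every cortex value, 67 remained at least 3-fold higher in cortex, above the highest count of 43 in matched lists of the same values, which argues against an even background as the whole source and leaves an uneven one open. Probes that report other transcripts of the cortex remain possible. Where the brightest second probe of a called gene lay above the floor on at least 1 array, it repeated the call for 26.1% of those higher in cortex and 31.6% of those higher in epithelium (Fisher's exact test across genes, two-sided p = 0.417). That test covers all called genes and not the receptor genes alone, few of which have a second probe, so it cannot decide the question for them. Probe sequences were not used here, and transcription of receptor genes in fiber cells was not tested.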
